A study of Mus musculus with 6 samples.

How the data were processed

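RNA sequencing was done on sorted mouse skin cells from 3 control and 3 Zfp750 knockout samples at day 50. Per the labels' protocols, the skin cells were sorted from mice that express the red fluorescent protein tdTomato, RNA was extracted with a PureLink column kit and libraries were made with the NEBNext Ultra II RNA kit. The knockout samples are labelled as carrying 2 floxed Zfp750 alleles and 1 Lrig1-CreER or Lrig1-CreERT2 allele, a tamoxifen-activated recombinase under control of the Lrig1 gene. All samples received 4-hydroxytamoxifen on days 4 to 7 or days 5 to 8 of age, per the labels. The control samples carry the same recombinase with 1 or no floxed Zfp750 allele. The labels give the Rosa26 genotype as -/- for all 3 knockout and for 2 of the control samples, and as +/- for the other control sample. Rosa26 is a usual site of tdTomato reporters, so the labels do not show how the cells carried tdTomato.

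The submitters' processing notes name TopHat2 2.1.0 and Partek 9.0.20.0202, without saying what each was used for. The genome build and the annotation release are not given in the sources used here. Of the 23934 gene IDs, 23221 (97.0%) occur in the GENCODE annotation of GRCm38, but 511 of these (2.20%) have the same start there, so positions from the table are given only as the table's own. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain. Related genes, such as Tpsab1 and Tpsb2, Saa1 and Saa3, and the small proline-rich genes, may share some reads, so their separate values may be uncertain.

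The authors deposited a single table of normalized counts, per the file headers, whose unit is treated here as a signal of estimated reads divided by one size factor per library. This reading comes from the values. In each library most values are whole multiples of one step, and the reciprocal of that step equals the median-of-ratios size factor (0.787 to 1.26). Of the values up to 1000 reads, 78.7% to 81.2% per library are whole reads within a tolerance of 0.05. The others are fractions, some of them minute, as an estimated assignment of shared reads leaves. The values are not scaled to a common total or to gene length, and the highest values, those of collagens, carry 3 significant digits. Every gene in the table sums to at least 10 estimated reads over the 6 libraries within rounding. Estimated depth was 15310176, 20705363 and 19224124 reads in the control libraries and 17061453, 16940652 and 20222365 in the knockout libraries. A floor of 3 reads corresponds to a normalized value of 2.39 to 3.81 by library. Intervals and floors cover counting error only.

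The names of the 6 value columns give the group but match no numbered sample, so the libraries are called control S2, S3 and S4 and knockout S5, S6 and S7 after the numbers in those names. Column numbers were used to pair libraries in 1 added alternative and nowhere else. The genotypes are given per sample, but nothing in the labels says outright that each library is a separate mouse, so p-values measure the spread between these samples, which may in part be technical. No 2 libraries were alike beyond the others: the Pearson correlation across genes was 0.929 to 0.971 within groups.

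Group differences were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, 2-sided) on log2(value + 9.15), the pseudocount being 0.5 per 1000000 of the mean library total. Genes had to reach 1 per 1000000 of the library total in at least 3 of the 6 libraries, which left 15935. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Fold changes are on the log2(value + pseudocount) scale, which understates the change of low genes. Adjusted p-values of single genes below are from this limma fit. Because the values are whole reads in part only, as given above, count models were not run. The design had foreseen a log-scale model for normalized values and count models only for whole reads.

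The test, filter, gene lists and the rule for naming genes were fixed before the data were examined. The rule took Zfp750, then the 10 largest rises and 10 largest falls by log2 fold change among called genes with separated groups and a mean of at least 5 per 1000000, leaving out predicted genes and pseudogenes. It also took up to 4 called members of each list by adjusted p, or the 2 with the highest mean where none was called. Krt5, Ptprc, Col1a1, Col1a2, Col3a1, S100a8, Adipoq, Pecam1 and Cd34 were named outside this rule, after their values were seen, as were the genes of families taken by name. A sebocyte list member that the rule takes is not reported here. Of 28 lists, 27 had at least 2 tested genes, and the erythrocyte list had 0 tested. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Shares of library totals were compared by exact 2-sided permutation tests over 20 assignments, whose smallest possible p is 0.1. The sex of the animals was read from Xist and Y-linked genes: control S3 and knockout S6 were female and the other 4 libraries male.

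The fit was tested on simulated data with the means, size factors and spread of the real genes for the knockout against control comparison, over 15967 genes with 200 changed. It recovered 10.2% of genes changed 2-fold, 70.0% of those changed 4-fold, 88.0% of those changed 8-fold and 85.7% of those changed 16-fold. In that simulation 16 of 142 calls were false, a larger share than the nominal 0.05. In a simulation of lists over 15896 genes, camera called all 4 lists raised 4-fold and 0 of 100 unchanged lists. Camera with an estimated correlation called the same numbers there, whereas it called 0 of the real lists. The estimated correlation of the real lists ran from -0.033 (cytokines and chemokines) to 0.893 (muscle). The simulation thus does not show how often camera at the preset correlation calls unchanged lists whose genes are correlated. Alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, leaving out each library in turn and the list test. Others, added after seeing the data, were a voom fit, leaving out control S4 with knockout S7, pairs by column number, and covariates for Krt5, Ptprc and sex. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.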

Results

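Transcriptomes of sorted skin cells, from mice labelled as expressing tdTomato, were measured at day 50 in 3 control libraries (S2, S3, S4) and 3 Zfp750 knockout libraries (S5, S6, S7), each of 15310176 to 20705363 estimated reads. Zfp750 encodes the mouse counterpart of ZNF750, a zinc finger transcription factor of epidermal differentiation. The recombinase was driven from Lrig1, a gene expressed in the upper hair follicle. Rosa26, a usual site of tdTomato reporters, is labelled -/- in 5 of the 6 samples, so the labels do not show how the cells carried tdTomato. The series title ties loss of the gene there and at the sebaceous gland to an inflamed skin disease, and the comparison asks how the sorted cells differed in transcript levels between the genotypes.

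Zfp750 (ENSMUSG00000039238, chromosome 11, start 121401804 in the table's own coordinates; 121510978 to 121519333 on the minus strand of GRCm38) was low in all 3 knockout libraries, at normalized values of 4.90, 1.82 and 7.16 in S5, S6 and S7. In the controls it was 41.9, 3.75 and 314 in S2, S3 and S4. These values stand for 33, 3 and 373 estimated reads in the controls and 5, 2 and 9 in the knockouts. The mean was 120 ± 169 in controls and 4.63 ± 2.68 in knockouts (SD, n = 3 each; exact permutation p = 0.3, smallest possible 0.1). Zfp750 did not pass the filter on low values, and a limma fit without the filter gave a log2 fold change of -2.13 ± 0.98 (SE) with an adjusted p of 0.275. Control S3 lay inside the knockout range, and its exact 95% Poisson interval of 0.773 to 11 overlapped those of all 3 knockout libraries, so Zfp750 does not check the label of that library. Control S3 also had little of the basal keratinocyte transcript Krt5 (62.5, against 2503 in S2 and 11805 in S4). Relative to Krt5, a ratio chosen after the values were seen, Zfp750 was 16.8, 60 and 26.6 per 1000 in the controls and 4.21, 2.06 and 0.837 per 1000 in the knockouts (exact permutation p = 0.1, the smallest possible). The value is per gene and does not tell deleted from remaining exons.

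**Figure D1:**
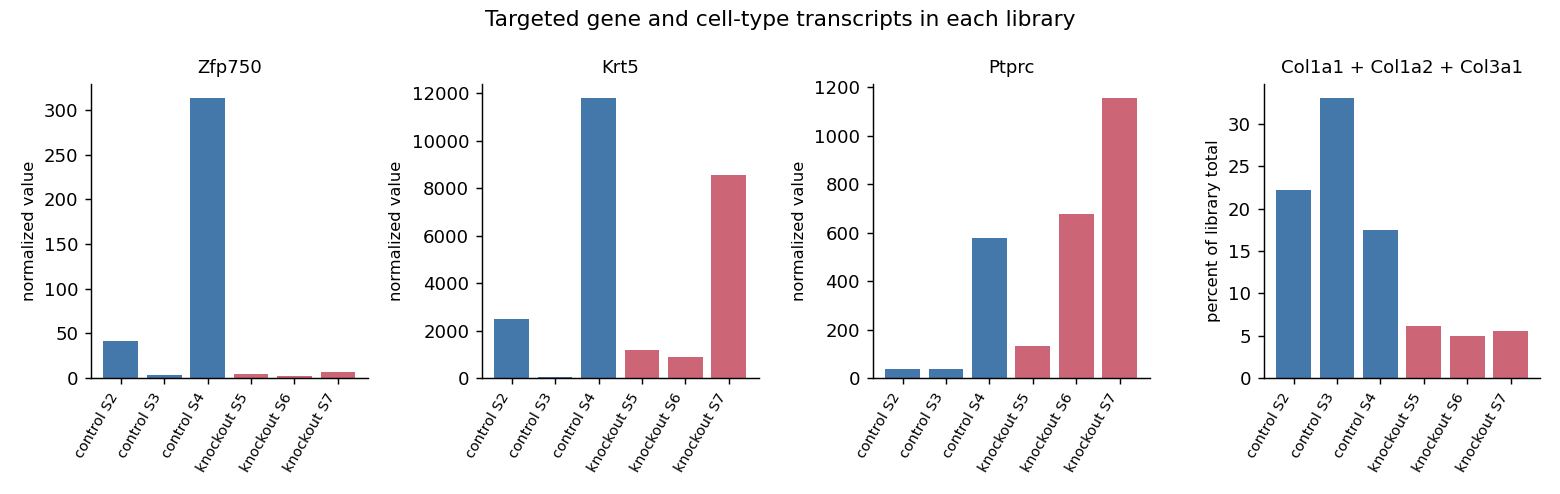
Bars give the normalized value of Zfp750, Krt5 and Ptprc and the percent of the library total held by Col1a1, Col1a2 and Col3a1 in each of the 3 control (blue) and 3 knockout (red) libraries; every axis starts at 0. Control S4 and knockout S7 hold the most Krt5 of their groups (11805 and 8559), and the 3 collagens take 17.5% to 33.1% of control and 4.96% to 6.18% of knockout totals.

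The most abundant transcripts of the libraries were those of fibrillar collagens, the main structural proteins of the dermis. Col1a1, Col1a2 and Col3a1 together took 24.3% ± 7.99 of the control totals and 5.55% ± 0.609 of the knockout totals (SD, n = 3 each; exact permutation p = 0.1, the smallest possible; adjusted 0.225 over 9 measures). The 10 highest genes of each library took 30.7% ± 8.03 in controls and 10.2% ± 0.812 in knockouts (exact permutation p = 0.1). As single genes, Col1a1 (log2 fold change -2.67 ± 1.21 SE, adjusted p = 0.237) and Col1a2 (-2.71 ± 0.92, adjusted p = 0.131) did not pass the limma test. Their groups did not overlap: Col1a1 was 1430000 to 4570000 in the controls and 333927 to 407741 in the knockouts. Col1a2 was 757292 to 2390000 and 185734 to 216530. The limma SE draws each gene's variance toward the trend over genes of its level, so it is not the spread of these genes alone. Ribosomal protein genes held 0.528% ± 0.108 of control and 0.798% ± 0.159 of knockout totals (exact permutation p = 0.1). Mitochondrially encoded transcripts held 0.745% ± 0.195 and 0.873% ± 0.169 (exact permutation p = 0.6), and ribosomal RNA genes 0.480% ± 0.177 and 0.380% ± 0.0872 (exact permutation p = 0.5). Libraries had 15290.0 ± 1193 genes at 1 per 1000000 or more in controls and 15924 ± 533 in knockouts (exact permutation p = 0.6), and estimated reads did not separate the groups (exact permutation p = 0.9). The pan-leukocyte transcript Ptprc was 36.9, 36.2 and 579 in the controls and 133, 679 and 1158 in the knockouts.

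The 10 largest rises taken by the rule for naming genes included Saa3, Mmp13 and Tnn, and the 10 largest falls included Miat. Saa3 (ENSMUSG00000040026, chromosome 7), an acute-phase serum amyloid, went from 2.67 ± 2.1 to 2600.3 ± 976 normalized units (SD, n = 3 each; log2 fold change 7.74 ± 0.29 SE, limma adjusted p = 4.14e-05). Mmp13, an interstitial collagenase (ENSMUSG00000050578, chromosome 9), went from 8.53 ± 2.39 to 2963 ± 311 (7.40 ± 0.19, adjusted p = 9.26e-06). The matrix glycoprotein gene Tnn, tenascin N, rose from 47.5 ± 45.8 to 10099 ± 3735 (7.70 ± 0.51, adjusted p = 0.000591). The long noncoding RNA Miat (ENSMUSG00000097767, chromosome 5) fell from 2687 ± 558 to 58.3 ± 15.8 (-5.33 ± 0.23, adjusted p = 9.08e-05).

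Across the transcriptome, 1070 of 15935 tested genes changed, 657 higher and 413 lower in the knockout, and 3697 had an unadjusted p under 0.05. More than 4-fold changes numbered 240 up and 155 down, and 992 of the changed genes were protein coding and 49 long noncoding. All 1070 had non-overlapping groups, as did 28.8% of tested genes, where chance gives 10%. Rescaling all libraries to a common total gave 1057 higher and 283 lower genes, or 78.9% higher against 61.4% as deposited, and moved the median log2 fold change of shared genes by 0.31, so changes are relative to the authors' scaling. Leaving out control S2, control S3, knockout S6 or knockout S7 lowered the count to 307, 545, 270 or 435.

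Among the other large rises were the haptoglobin gene Hp (log2 fold change 6.09 ± 0.76 SE, adjusted p = 0.00599), Prg4, which encodes lubricin (6.03 ± 0.35, adjusted p = 0.000304), the osteopontin gene Spp1 (5.98 ± 0.31, adjusted p = 0.000239), the hyaluronan-degrading Cemip (5.92 ± 0.33, adjusted p = 0.000296) and the hormone gene Fgf23 (5.87 ± 0.22, adjusted p = 4.14e-05). Cbln1 was at 0 in all 3 controls and at 463, 1074 and 1678 in the knockouts, at least 318.8-fold higher against a floor of 3 reads per control library (limma adjusted p = 0.000578). Fcgbp (5.96 ± 1.34, adjusted p = 0.0433) lost its call without S2, S3, S5, S6 or S7, with adjusted p-values of 0.138, 0.0885, 0.0537, 0.111 and 0.104. Falls included Arfgef3 (-5.14 ± 0.50, adjusted p = 0.00238), the cadherin Cdh4 (-5.00 ± 0.60, adjusted p = 0.00543), Lgi1 (-4.97 ± 0.41), Colq (-4.80 ± 0.63), Gpha2 (-4.61 ± 0.58), Lypd1 (-4.15 ± 0.53) and the prostaglandin-degrading enzyme gene Hpgd (-4.34 ± 0.43), the last 5 with adjusted p-values of 0.00135 to 0.00702. Lrrtm4 (-4.29 ± 0.84, adjusted p = 0.0281) lost its call without S2, S6 or S7, at adjusted p-values of 0.0994, 0.119 and 0.0916. Creb3l3 (-4.17 ± 0.59, adjusted p = 0.00879) lost its call without S2 or S6, at 0.0534 and 0.0510.

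**Figure D2:**
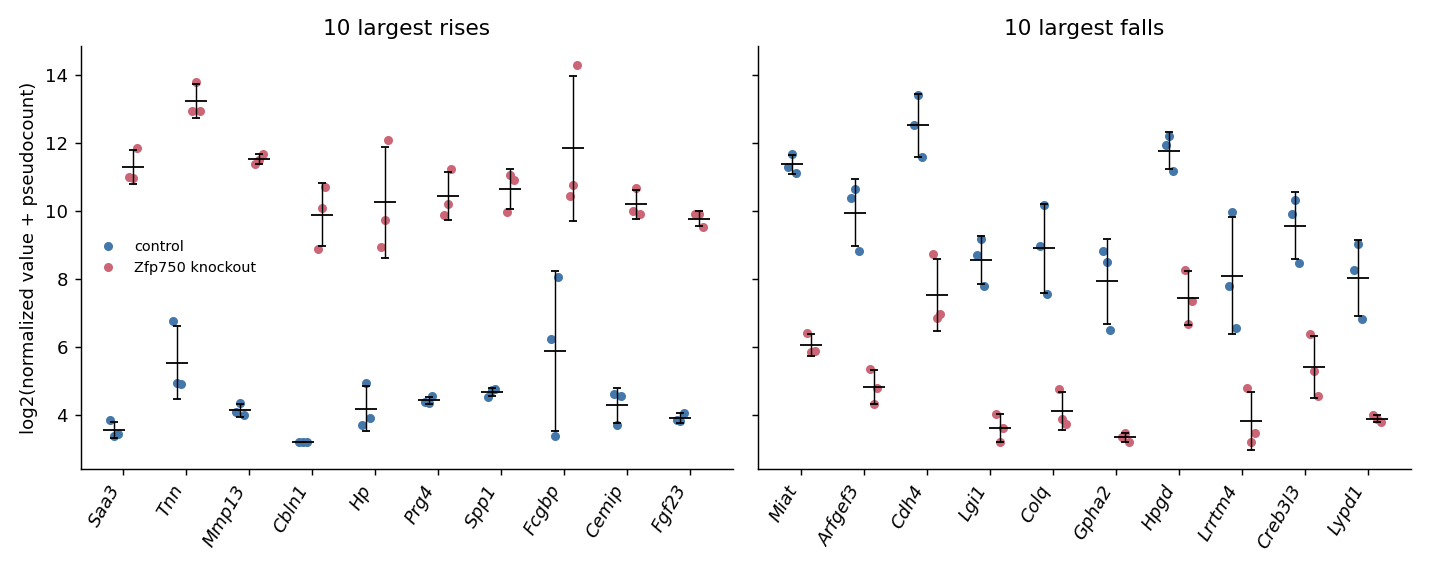
Points give log2(normalized value + 9.15) per library for the 10 largest rises and 10 largest falls in 3 control (blue) and 3 knockout (red) libraries; dashes are means and error bars SD. The groups do not overlap for any of the 20 genes, as the rule for naming genes required, and Fcgbp has the widest spread (SE 1.34).

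Of 16 tested genes on the list for keratinocyte activation and alarm, 5 rose and 0 fell in the knockout, with 10 rising when adjusted over the list alone. The name of the list does not give the source of these transcripts, and which cell type carried the rises was not tested. Beside Saa3, the antibacterial lipocalin gene Lcn2 rose from 5.74 ± 2.17 to 642 ± 339 normalized units (SD, n = 3 each; log2 fold change 5.34 ± 0.37 SE, adjusted p = 0.000661). The protease inhibitor gene Slpi rose to 190 ± 107 (3.90 ± 0.50, adjusted p = 0.00608) and the cross-linking enzyme gene Tgm1 to 265 ± 72.2 (3.33 ± 0.27, adjusted p = 0.00124). Among 23 tested cytokine and chemokine genes 5 rose and 1 fell (7 and 1 over the list alone). The neutrophil-attracting Cxcl5 went from 1.26 ± 1.27 to 228 ± 152 (4.33 ± 0.44, adjusted p = 0.00283). The alarmin Il33 was 1.59 ± 0.29 higher (adjusted p = 0.0219), a call lost without S2, S3 or S7 at adjusted p-values of 0.0841, 0.0527 and 0.0698. The fall was in the interleukin gene Il18 (-1.69 ± 0.35, adjusted p = 0.0320), a call lost without S2, S3, S4, S6 or S7 (adjusted p = 0.0614 to 0.118). Cxcl2 lost its call without S3, S4, S6 or S7 (adjusted p = 0.0543 to 0.138). Camera called the alarm list (adjusted p = 3.17e-06) and the cytokine list (adjusted p = 0.0135), and neither with an estimated correlation (adjusted p = 0.534 for each). Without S5, S6 or S7 the alarm list had adjusted p-values of 0.283, 0.262 and 0.138, and without S5 or S6 the cytokine list had 0.0644 and 0.102. Without 1 knockout library, Saa3, Lcn2, Slpi and Cxcl5, near 0 in the controls, fell below the filter, which still asked for 3 libraries. Both lists were thus tested there without these members. The mean log2 level of the alarm list was 5.53, 4.06 and 6.20 in S2, S3 and S4 and 6.77, 7.17 and 8.51 in S5, S6 and S7.

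Mast cell and neutrophil markers were higher in the knockout. Of 9 tested mast cell genes 5 rose and 0 fell, and all 9 rose when adjusted over the list alone (camera adjusted p = 2.00e-06; adjusted p = 0.534 with an estimated correlation). The tryptase gene Tpsab1 was at 0 in all controls and at 151, 998 and 291 in the knockouts, at least 142.8-fold higher against a floor of 3 reads per control library (adjusted p = 0.00455). The IgE receptor gene Fcer1a was likewise at 0 in the controls and at least 27.8-fold higher (adjusted p = 0.0148), a call lost without S2 (adjusted p = 0.0666). The tryptase gene Tpsb2 was at 2.54, 8.74 and 65.6 in controls S2, S3 and S4 and at 276, 1385 and 450 in the knockouts. Control S4 thus held tryptase transcript, and the bound for Tpsab1 does not measure a rise in mast cells. Tpsb2 lost its call without S2, S3, S6 or S7 (adjusted p = 0.0589 to 0.0813). Of 5 tested neutrophil genes 3 rose, Mmp9, Mmp8 and Hdc, and 5 over the list alone (camera adjusted p = 9.58e-05; adjusted p = 0.534 with an estimated correlation). The gelatinase gene Mmp9 rose from 14.6 ± 4.19 to 1248 ± 466 normalized units (5.68 ± 0.29, adjusted p = 0.000239). Hdc, which the mast cell list also counts, lost its call without S2, S3, S6 or S7 (adjusted p = 0.0684 to 0.102). Mmp8 lost it in each fit that tested it, those without S2, S3 or S4 (adjusted p = 0.125, 0.0670 and 0.0534). S100a8, an abundant neutrophil transcript that did not pass the filter and was chosen after its values were seen, was at 11.8, 25.5 and 225 in the knockouts, below Mmp9 in each.

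T cell and macrophage marker lists were higher by camera although no member of either passed the test. The T cell list of 17 tested genes had a median log2 fold change of 1.75 (camera adjusted p = 0.000965; adjusted p = 0.627 with an estimated correlation), with Icos at 2.64 ± 0.73 (adjusted p = 0.0773). This call was lost without S6 (adjusted p = 0.154) or S7 (adjusted p = 0.160), the median being 0.99 without S7. The macrophage list of 15 had a median of 2.02, or 1.20 without S7 (camera adjusted p = 0.000906; adjusted p = 0.615 with an estimated correlation), with Lyz2 at 2.02 ± 1.01 (adjusted p = 0.280). The mean log2 T cell level of control S4, 5.59, lay above that of knockout S5, 4.64. For Langerhans and dendritic cells 1 of 7 rose and 1 fell (2 and 1 over the list alone), for class II antigen presentation 1 of 10 rose, and camera called neither list (adjusted p = 0.107 and 0.111), though class II was called higher without S4 (adjusted p = 0.000632). The milk fat globule gene Mfge8 rose 1.58 ± 0.15 (adjusted p = 0.00238). The decoy interleukin-1 receptor gene Il1r2 fell by 2.44 on the log2 scale (SE 0.35, adjusted p = 0.00923; adjusted p = 0.0550 without S6) and Cd40 rose 2.82 ± 0.33 (adjusted p = 0.00455). The interferon list, with 1 of 39 genes up and 1 down, and the pattern recognition receptors, with 2 of 32 up and 2 down (4 and 4 over the list alone), were not called (camera adjusted p = 0.265 and 0.593). Without S3 or S7 the interferon list was called higher (adjusted p = 0.0315 and 0.0185). Casp1, 1 of these 6 genes, lost its call without any 1 of the libraries (adjusted p = 0.0513 to 0.173). The other 5 lost theirs in 2 to 5 of these 6 fits.

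Of 26 tested sebocyte genes 5 rose and 1 fell (7 and 1 over the list alone; camera adjusted p = 0.000763; adjusted p = 0.615 with an estimated correlation). The median log2 fold change of that list was 0.74, and without S7 it was 0.088 and the list was not called (adjusted p = 0.0766). Elovl3 and Awat1 fell below the filter in that fit, so the list was tested without them. Plin2 lost its call without S2, S3, S5, S6 or S7 (adjusted p = 0.0502 to 0.0764) and Awat1 without S2 or S3 (0.0781 and 0.0651). The very long chain elongase gene Elovl3 rose from 6.85 ± 2.78 to 254 ± 214 normalized units (3.76 ± 0.52, adjusted p = 0.00827). Of 21 epidermal ceramide genes 4 rose and 1 fell (6 and 1 over the list alone; camera adjusted p = 0.0160; adjusted p = 0.615 with an estimated correlation; 0.0677 without S4 and 0.0641 without S7). Among them the elongase gene Elovl4 rose 5.25 ± 0.82 (adjusted p = 0.0124; 0.0568 without S6). Fa2h lost its call without S2, S3, S6 or S7 (adjusted p = 0.0574 to 0.0973) and Ugcg without S2 or S6 (0.0648 and 0.0769). Cerk, the 1 that fell, lost it without S2, S3, S5, S6 or S7 (0.0861 to 0.133). Of 26 cholesterol synthesis genes 1 rose, 0 over the list alone, and 23 had a positive log2 fold change (camera adjusted p = 0.000763; adjusted p = 0.615 with an estimated correlation). The 1 was Sqle, whose call was lost without S2, S4, S5, S6 or S7 (adjusted p = 0.0785 to 0.156). Of 22 glycolysis and hypoxia genes 3 rose, and 10 over the list alone (camera adjusted p = 0.000763; adjusted p = 0.534 with an estimated correlation). Of the 3, Ldha and Pkm lost their calls without any 1 of the 6 libraries (adjusted p = 0.0607 to 0.173 and 0.0577 to 0.185). Their log2 fold changes stayed at 0.59 to 0.77 and 0.70 to 0.98 in these fits. Pfkfb3 lost its call without S2, S3, S6 or S7 (0.0540 to 0.112). The fat cell markers, of which Cfd rose among 5 tested (4 over the list alone), were called (camera adjusted p = 0.0456; adjusted p = 0.615 with an estimated correlation), and not without S2, S4, S5, S6 or S7 (adjusted p = 0.0520, 0.0651, 0.353, 0.325 and 0.361). Cfd lost its call in each fit that tested it, those without S2, S3 or S4 (adjusted p = 0.138, 0.0951 and 0.0513). The fits without S5, S6 or S7 tested the fat cell list without Cfd. Adipoq, a fat cell transcript outside the naming rule and chosen after its values were seen, was 6.86, 111 and 519 in knockouts S5, S6 and S7 and 0 to 2.52 in the controls.

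Of 17 tested cornified envelope and differentiation genes 2 rose and 1 fell (3 and 2 over the list alone), and camera did not call the list (adjusted p = 0.165): the transcriptional repressor gene Prdm1 rose 4.27 ± 0.37 (adjusted p = 0.00159) with Tgm1. The suprabasal keratin gene Krt10 fell by 1.77 (SE 0.42, adjusted p = 0.0496), a call lost without S2, S3, S4, S6 or S7 (adjusted p = 0.0890 to 0.147). Of 21 basal keratinocyte genes 1 rose, the anchoring fibril collagen gene Col7a1, from 534 ± 68.5 to 7536 ± 2213 normalized units (3.76 ± 0.25, adjusted p = 0.000578), and the list was not called (camera adjusted p = 0.265). Of 16 bulge stem cell genes 5 rose and 1 fell (camera adjusted p = 0.151): Runx1 rose 2.60 ± 0.30 (adjusted p = 0.00449) and Dkk3 2.19 ± 0.24 (adjusted p = 0.00361). Cd34, chosen after its values were seen, fell by 2.17 (adjusted p = 0.0222). Postn lost its call without S2 or S6 (adjusted p = 0.0707 and 0.0510) and Col24a1 without S6 (0.0519). The other 10 bulge genes did not pass the test. Fibroblast markers had higher mean log2 levels than basal keratinocyte markers in every library (15.1 to 16.1 against 7.96 to 10.9). Which cell type carried the changes in Col7a1 and the bulge list genes was not tested. In the upper follicle and junctional zone list 0 of 11 passed (2 over the list alone), with Lrig1 at 0.47 ± 0.45 (adjusted p = 0.575). Camera called that list (adjusted p = 0.0285; adjusted p = 0.705 with an estimated correlation), but not without S3 (adjusted p = 0.520) or S7 (adjusted p = 0.116). Of 25 hair shaft and inner root sheath genes, 7 passed the filter, 0 of them changed and the list was not called (camera adjusted p = 0.484). Without the filter its median turned from 0.74 to -0.93 and it was called lower (adjusted p = 0.00291). The genes that the filter had dropped from this list were each highest in control S4, and the lower call was not tested without S4. Cell cycle genes (0 of 39) and immediate early genes of cell dissociation (0 of 22) had no member past the limma test, with camera adjusted p-values of 0.309 and 0.496. The cell cycle list was called lower without S2 or S3 (adjusted p = 0.00906 and 0.0482) and higher without S4 (0.0270), and the immediate early list higher without S7 (0.0137). Without S4 the cornified envelope, basal and bulge lists were called higher (adjusted p = 0.0283, 0.0154 and 0.0374). The keratin gene Krt5 had a log2 fold change of 0.69 ± 1.76 (adjusted p = 0.851), with S4 and S7 the highest libraries of their groups.

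Other cell types of the skin went different ways. Of 19 fibroblast genes 2 rose, the growth factor receptor genes Pdgfra, from 11100.0 ± 332 to 26291 ± 2887 normalized units (1.24 ± 0.21, adjusted p = 0.0165), and Pdgfrb (1.00 ± 0.22, adjusted p = 0.0384), while the list was not called (camera adjusted p = 0.414) except, as lower, without S4 (adjusted p = 0.0485). Pdgfra lost its call without S2, S6 or S7 (adjusted p = 0.0994, 0.0619 and 0.0640) and Pdgfrb without any 1 of the 6 libraries (highest adjusted p = 0.138). Of 12 endothelial genes 1 rose, the vascular receptor gene Flt1, from 69.7 ± 29.2 to 2332 ± 808 (4.90 ± 0.37, adjusted p = 0.000858), with 4 over the list alone (camera adjusted p = 0.00168; adjusted p = 0.615 with an estimated correlation). Skeletal muscle was the list called lower, with 0 of 10 genes past the test and 2 over the list alone (camera adjusted p = 0.00247; adjusted p = 0.615 with an estimated correlation). Acta1 was 272, 2569 and 4277 in the controls and 727, 216 and 789 in the knockouts. Melanocyte and Schwann cell genes (0 of 11; camera adjusted p = 0.331) and Merkel cell genes (1 of 5 up and 1 down; camera adjusted p = 0.975) were not called, though Krt20 fell by 2.83 (SE 0.37, adjusted p = 0.00684) and Piezo2 rose 1.86 (adjusted p = 0.0204; 0.0767 without S6). The Merkel list had a positive median, 0.69, and a downward fry direction, and was called higher without S2 (adjusted p = 0.0269).

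**Figure D3:**
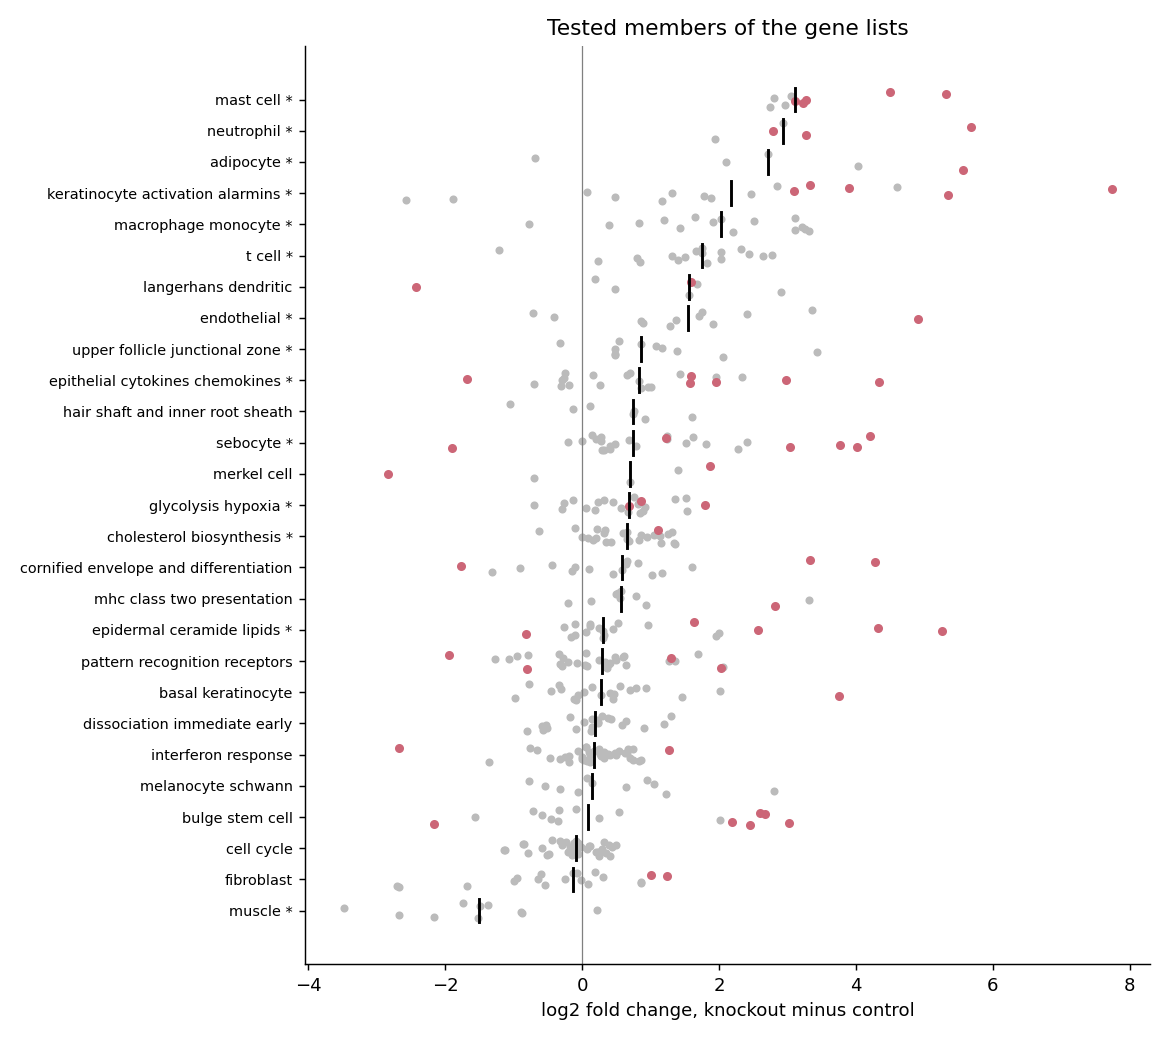
Each point is the log2 fold change of 1 tested gene in each of the 27 lists, red where the gene passed an adjusted p of 0.05 and grey otherwise; black lines are list medians and an asterisk marks lists called by camera at the preset correlation. The medians run from 3.11 for mast cells to -1.51 for muscle (-2.37 without S2 and -0.89 without S4).

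Of the 27 lists, camera called 13 higher and 1 lower, fry called 3 (the alarm, neutrophil and cytokine lists) and camera with an estimated correlation called 0, its lowest adjusted p being 0.534. For change in either direction, fry called 18 lists. Where no count over the list alone is given, it equals that over all genes.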

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

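The voom fit, the joint omission of S4 and S7, the column-number pairs and the covariate fits were chosen after seeing the data; the other alternatives were planned. All 1070 called genes kept their sign in each setting in which they were tested. Their groups did not overlap, so leaving out libraries or changing the pseudocount, filter or variance model could not have turned a sign. Of 1696 values of named genes over 22 settings, 1438 stayed on their side of the threshold, 227 lost and 15 gained a call and 16 turned in direction. Of 644 list values, 528 stayed, 71 lost and 21 gained a call and 24 turned, and 0 of the turns were of called genes or lists. For lists, a turn means that the direction of the list test changed. The median of the called cytokine list, 0.82, went as low as -0.018 over the settings without a turn of its test. Counts of changed genes stayed within 1.5 times the main count for both pseudocounts (1029 and 1014), no filter (988), a stricter filter (989), quantile normalization (1168, with 617 higher and 551 lower, 52.8% higher), no trend (864), robust variance (1043), voom (790), the fits without S4 and S7 (866, of which 597 shared) and with sex (887) or Krt5 (1495). Rescaling by median of ratios left all 1070, as it had to, since the deposited values already carry these size factors. Its 83 gene and 27 list values, all of which stayed, are among the totals above and test nothing. Planned count models were not run, since part of the values are not whole reads. No paired analysis was possible because the columns cannot be matched to the numbered titles. Another number, the one in the column names, is shared by 2 pairs of libraries, and no label says what it stands for. The fit added on these 4 libraries gave 1278 changed genes (611 higher and 667 lower). The 2 pairs joined a male and a female library each, with deviation correlations of 0.25 and -0.22.

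Leaving out 1 library gave 270 to 1237 changed genes, 179 to 697 higher and 74 to 540 lower, with 9 to 16 lists higher and 1 to 2 lower. Such a fit has a degree of freedom less, so a call near the threshold can be lost with little change in its estimate. A lost call thus does not by itself show that the result came from the library left out. The filter still asked for 3 libraries, so 21 of the 67 called named genes, Saa3 and Cbln1 among them, fell below it in some of these fits; of the 46 tested in all 6, 15 kept their call in each. Ranges that crossed 0, or whose list test turned, were -0.10 to 0.80 for Lrig1, -1.88 to 2.19 for Krt17, -0.16 to 0.081 for Pcna and -0.90 to 0.83 for Mki67. For list medians they were -0.29 to 0.69 for basal keratinocytes, 0.027 to 0.29 for pattern recognition receptors, -0.39 to 0.38 for the cell cycle, 0.011 to 0.40 for immediate early genes, -0.015 to 1.33 for Merkel cells, -0.20 to 1.13 for the cornified envelope, -0.14 to 0.79 for the bulge and -0.031 to 0.30 for interferon response. Medians of called lists that moved by over 1.5 times without 1 library went from 2.17 to 0.76, 0.79 and 0.81 for the alarm list (without S5, S6 and S7), from 0.86 to 0.46 and 1.54 for the junctional zone (S3 and S4) and from 0.65 to 0.41 for cholesterol synthesis (S2). Without S7 they went from 0.74 to 0.088 for sebocytes, 1.75 to 0.99 for T cells, 2.02 to 1.20 for macrophages, 1.54 to 0.84 for endothelium and 2.72 to 1.53 for fat cells. These medians are not all over the same genes. Without 1 knockout library, Saa3, Lcn2 and Slpi left the alarm list, Elovl3 and Awat1 the sebocyte list and Cfd the fat cell list. The muscle median, -1.51, was -2.37 without S2 and -0.89 without S4. The difference in genes at 1 per 1000000 ran from -8 to 1170.5. The Zfp750 log2 difference ran from -3.31 to -0.91, and the pseudocount moved it from -2.81 to -1.33.

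With library weights the counts were 1997 changed, 1132 higher and 865 lower, 0 lists lower, and Krt17 -0.32, Mki67 0.23, cell cycle 0.27 and Merkel list 0.45. Scaling to a common total gave 1057 higher, Pcna 0.25, Mki67 0.0075 and Merkel list 0.89. With no filter 2 lists were lower, the hair shaft median was -0.93 and that list was called lower (adjusted p = 0.00291); the stricter filter left 0 lower; under quantile normalization the fibroblast test turned, with a median of -0.098. An estimated correlation called 0 lists higher and 0 lower, and fry 3 and 0, with the Merkel list (median 0.69) turned. Without S4 and S7, 8 lists were higher, Mki67 was 0.47 and the cell cycle 0.18. Column-number pairs gave 2 lists lower, Mki67 0.80, interferon -0.089, pattern recognition -0.20, cell cycle 0.31 and immediate early genes 0.022. The Krt5 covariate turned Krt17 to -0.24 and the Merkel list test (median 0.64). The Ptprc covariate gave 479 changed, 339 higher and 140 lower genes and 2 lists lower. It turned Krt17 to -1.87, Gata3 to -0.73, Pcna to 0.0066, cornified envelope to -0.75, basal keratinocytes to -0.86, hair shaft to 0.034, class II presentation to -0.90, fibroblasts to 0.20 and the Merkel list test (median 0.13). Beside the lists called without 1 library, calls gained were class II presentation with no filter, library weights, S4 and S7 left out or pairs (adjusted p = 0.0250, 0.0464, 0.00395 and 0.00348) and the bulge with S4 and S7 left out (0.0388). Pairs also called basal keratinocytes and the cell cycle higher and fibroblasts lower (0.00404, 0.0368 and 0.0292). The Ptprc covariate called interferon and immediate early genes higher and the cell cycle lower (0.00343, 0.0232 and 1.91e-06). The cause of these shifts was not tested. Depth limits low genes such as Zfp750, with 2 to 9 reads in the knockouts.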

Other observations

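All tests and gene families below were chosen after the data were seen. Beyond the lists fixed in advance, 13 families of genes taken by name were tested. Fisher's exact test called 11 of them, camera 4, and camera with an estimated correlation 0 (lowest adjusted p = 0.169). Of 18 tested matrix metalloproteinase genes, 8 rose and 2 fell, 55.6% against 6.71% of all tested genes (Fisher's exact test, adjusted p = 3.10e-07 over 13 families; camera adjusted p = 0.000104; adjusted p = 0.169 with an estimated correlation). Mmp11 went from 452 ± 50.4 to 13615 ± 1134 normalized units (SD, n = 3 each; log2 fold change 4.89 ± 0.16 SE, limma adjusted p = 2.49e-05), while Mmp27 fell from 1697 ± 695 to 174 ± 58.6 (-3.17 ± 0.38, adjusted p = 0.00529). Of 34 collagen genes 9 rose and 5 fell (Fisher's exact test, adjusted p = 1.77e-07), and camera did not call them in one direction (adjusted p = 0.602; adjusted p = 0.723 with an estimated correlation). Col12a1 rose from 4307 ± 1220 to 98462 ± 32994 (4.49 ± 0.36, adjusted p = 0.00116), and the basement membrane genes Col4a3, Col4a4, Col4a5, Col15a1 and Col18a1 fell, Col4a4 from 1107 ± 156 to 148 ± 94.1 (-2.98 ± 0.37, adjusted p = 0.00601). The tenascin gene Tnc rose from 1680 ± 1605 to 55786 ± 5631 (5.50 ± 0.62, adjusted p = 0.00414). Of 5 lysyl oxidase genes 0 changed (Fisher's exact test, adjusted p = 1), and of 17 ADAMTS protease genes 2 rose and 2 fell (adjusted p = 0.0412; camera adjusted p = 0.794; adjusted p = 0.879 with an estimated correlation). Genes of one family are not independent, and Fisher's test treats them as if they were.

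Of 26 tested interleukin receptor genes 7 rose and 1 fell (Fisher's exact test, adjusted p = 0.000916; camera adjusted p = 0.00226; adjusted p = 0.169 with an estimated correlation). Il1rl1, which encodes the receptor of interleukin-33, rose 4.06 ± 0.73 (adjusted p = 0.0207) and the decoy receptor gene Il13ra2 3.15 ± 0.44 (adjusted p = 0.00871), while Il1r2 fell by 2.44 (SE 0.35). Wnt ligand and antagonist genes had 4 up and 2 down of 19 (Fisher's exact test, adjusted p = 0.00373), and camera did not call them in one direction (adjusted p = 0.135; adjusted p = 0.266 with an estimated correlation).

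The 657 genes higher in the knockout could reflect RNA from other cells carried in the sort. With a term for the pan-leukocyte gene Ptprc, the median ratio of their log2 fold changes to those without the term was 0.951, and all 657 stayed positive, while the T cell median went from 1.75 to 0.49. The calls among them went from 657 to 313 as their median SE went from 0.26 to 0.30 and a degree of freedom was lost, with a median log2 fold change of 1.61 before and 1.54 after. The 657 genes were called partly for a small spread within groups, and the slope of the term comes from that spread. A ratio near 1 was therefore favoured in advance. The T cell genes, 0 of them called, were not selected in this way. The fit thus does not decide whether leukocyte RNA was a source, and an effect of the genotype and other sources that part the groups stay open. In knockouts S5 and S6, 21 basal keratinocyte genes lay on average at -0.85 ± 0.33 (SE, log2) relative to controls S2 and S4. This SE runs over genes and not over libraries. The mean list level was 9.31 and 9.39 in S5 and S6, and 9.54 and 10.87 in S2 and S4. All 657 genes were higher in S5 and S6, as their non-overlapping groups required. Control S3, low in Krt5, and knockout S7, high in it, were left out after their values were seen. Over all 6 libraries the mean log2 fold change of that list was 0.417. Basal keratinocyte RNA was thus not higher in S5 and S6 than in S2 and S4. Whether it was a source over all 6 libraries is not decided. For 17 cornified envelope and differentiation genes the mean of S5 and S6 relative to S2 and S4 was -0.25 ± 0.48 (SE over genes). RNA of differentiated keratinocytes and an effect of the genotype thus cannot be told apart. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many as 1070 changed genes and the highest of the others gave 0, but 10 splits are too few for a share under 0.05.

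Higher marker lists of mast, neutrophil, endothelial and fat cells could come from a smaller share of fibroblasts, which would raise all other types alike. The mast cell list minus the muscle list was -1.91, -3.82 and -2.96 on the log2 scale in the controls. It was 1.13, 3.57 and 1.75 in the knockouts, a shift of 5.04 between groups. These lists had the highest and lowest median log2 fold change of the tested lists (3.11 and -1.51), so their choice favoured a large shift. The muscle level was 5.92, 7.93 and 8.83 in S2, S3 and S4 and 6.24, 5.52 and 6.11 in S5, S6 and S7. The shift thus does not decide whether a smaller share of fibroblasts was the source. Mean log2 list levels parted the groups for mast cells (7.37 to 9.09 in the knockouts, 4.02 to 5.87 in the controls), neutrophils (6.63 to 8.50 and 3.89 to 4.54), endothelium (7.60 to 9.74 and 6.63 to 7.30) and fat cells (7.50 to 10.64 and 6.02 to 6.52). The T cell and macrophage levels overlapped, the lowest knockout T cell level less the highest control one being -0.96. More cells of these types among the sorted cells, against higher expression per cell, cannot be told apart, since cell numbers per type were not analysed here.

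No explanation was tested for the smaller part of the knockout libraries held by Col1a1, Col1a2 and Col3a1. The mean log2 level of the fibroblast markers, 15.1 to 16.1 in the 6 libraries, exceeded that of the basal keratinocyte markers, 7.96 to 10.9. How the fibroblast transcripts entered the libraries was not tested.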
